A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

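RNA was sequenced from purified B220+ spleen cells of mice in 4 genotypes: wild type, Dpy30+/- (1 Dpy30 allele disrupted), Eu-Myc (a transgene that drives Myc from the immunoglobulin heavy chain enhancer) and both alterations together, written here as Eu-Myc Dpy30+/-. Each genotype had 4 libraries, 16 in all. Per the labels, ERCC spike-in RNA was added at one ratio to cell number and polyadenylated RNA was selected before library preparation. The 6 human P493-6 B cell line samples (chromatin immunoprecipitation of Myc and H3K4me3, and input, with and without Dpy30 knockdown) were not analysed here.

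The deposited gene tables hold raw counts, 1 column per library, for 39179 Ensembl mouse genes and 92 ERCC spike-ins, followed by 5 summary lines of the counting program. The submitters' processing notes name CASAVA 1.8.4, TopHat2 2.0.13, HTSeq 0.6.0, DESeq and R, with the mouse builds GRCm38 and mm10. The annotation release and the strand setting were not given in the sources used here. All 16 library tables were identical to the columns of the merged table. Symbols were matched by Ensembl identifier for 37607 genes, and genes without a symbol held 0.430% of the counts. Replicate columns of a group differed by more than counting error, with a lowest chi-square per degree of freedom of 5.00 over all pairs. Gene counts per library ran from 23683790 to 34102965 with a median of 28646500. ERCC counts ran from 158460 to 1686378. Library numbers 1 to 8 held no transgene and 9 to 16 all held it, so that no batch term could be fitted across that division.

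Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test, group means for all 16 libraries in 1 fit), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a gene in the text is from that edgeR fit unless another tool is named. The contrasts were Eu-Myc against wild type, Dpy30+/- against wild type, Eu-Myc Dpy30+/- against Eu-Myc, Eu-Myc Dpy30+/- against Dpy30+/-, and the interaction of both alterations. Changes are log2 fold changes with the standard error (SE) of the fit. Levels are CPM (counts scaled to a common library size) with the standard deviation (SD) of 4 libraries.

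The contrasts, the tests, the rule for naming genes and 35 gene lists were chosen before the data were examined. The lists held 707 genes, of which 6 were not in the table. They covered COMPASS subunits, the Myc network, ribosome biogenesis, nucleotide synthesis, polyamine synthesis, translation factors, cytosolic ribosomal proteins, glycolysis, mitochondrial chaperones with import and oxidative phosphorylation, G1/S and DNA replication, and G2/M and mitosis. Further lists covered the p53 pathway, pro-apoptotic and anti-apoptotic genes, CDK inhibitors, pan-B, B cell progenitor, follicular, marginal zone, germinal centre and plasma cell genes, B cell receptor signalling, MHC class II, NF-kappaB, interferon response, and immediate-early genes. Markers of other cell types were T, NK, monocyte and macrophage, neutrophil, dendritic, erythroid, platelet, and stromal cells, and the mitochondrially encoded transcripts formed the last list. Lists were tested with camera of limma 3.58.1 (preset inter-gene correlation 0.01, at least 5 members, adjustment over the lists of a comparison), again with an estimated correlation, and with fry. Camera compares a list with all other genes, and fry asks whether its members move on balance one way.

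Dpy30 and Myc were always named. Other named genes passed the threshold with an average log2 CPM of at least 2 and no overlap between the groups' libraries, and were the 10 with the largest rise and the 10 with the largest fall, leaving out predicted genes, clones, pseudogenes, spike-ins and antigen receptor segments. Where fewer than 5 passed, the 5 with the smallest p were also named. Up to 4 members with the smallest p were named for each list described. A few of these members are not reported here. Kcnip3 lies below the level minimum and was named after its values were seen because few genes passed. The 3 immunoglobulin segments Igkv5-39, Ighg2b and Igha were also named after their values were seen.

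Counts of mouse genes per ERCC count, shares of counts and largest shares of 1 variable gene among Ighv (108 genes) and Igkv (103 genes) were compared between groups with two-sided exact permutation tests of 4 against 4 libraries, which have 70 assignments and cannot give a p below 0.0286, with adjustment over the 4 pairwise comparisons. Transgene effects with and without the Dpy30 alteration were compared by a slope through the origin (total least squares) across genes and by 100 relabellings of Dpy30 genotype within transgene status. The effect of the Dpy30 alteration on transgene-changed genes was computed with the Eu-Myc libraries divided into separate sets for gene choice and effect.

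Alternatives were RLE size factors, scaling to ERCC counts, leaving out immunoglobulin and haemoglobin genes, no low-count filter, a stricter filter (1 CPM in 8 libraries), DESeq2 1.42.0, limma voom with quality weights, fits of only the groups compared, and leaving out each library in turn. A term for Y-linked transcripts, leaving out 3 libraries that stand apart together (Dpy30+/- replicate 1, Eu-Myc replicate 1 and Eu-Myc Dpy30+/- replicate 4), and the stratified test of the spike-in ratio were added after the data were seen. The edgeR procedure was tested on simulated data for the contrast of Eu-Myc Dpy30+/- against Eu-Myc. Each gene was drawn independently, and 200 genes with an average log2 CPM of at least 2 were changed. Over 10 simulations the procedure recovered 75.7% of genes changed 1.5-fold and 95.7% of those changed 2-fold, with 4.71% false calls.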

Results

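Transcripts were counted in B220+ spleen cells of 4 mouse genotypes with 4 libraries each: wild type, Dpy30+/-, Eu-Myc and Eu-Myc Dpy30+/-. Dpy30 is a shared core subunit of the COMPASS complexes, which methylate histone H3 at lysine 4, and the Eu-Myc transgene drives the transcription factor Myc in B lineage cells. The series title names the question of whether Dpy30 affects Myc's targets and Myc-driven tumours. Gene counts per library ranged from 23683790 to 34102965. The variation between replicates beyond counting error (biological coefficient of variation) was 13.2% in wild type, 15.8% in Dpy30+/-, 13.4% in Eu-Myc and 14.1% in Eu-Myc Dpy30+/-. The labels do not say that the replicates of a genotype are separate animals, so the p-values measure only the spread between these samples. Y-linked transcripts were present in 3 of 4 wild-type, 2 of 4 Dpy30+/-, 1 of 4 Eu-Myc and 1 of 4 Eu-Myc Dpy30+/- libraries. Among the 1000 most variable genes, the first principal component held 87.8% of the variance and separated the libraries with the transgene from those without it. The second held 4.33%, with a negative score in each library that had Y-linked transcripts and a positive score in each that lacked them. Sex-linked genes were not left out of the choice of these 1000 genes. This division may therefore rest in part on the sex-linked transcripts themselves.

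Dpy30 (ENSMUSG00000024067, chromosome 17, 74299474 to 74323944, GRCm38.p6) stood at 23.9 ± 2.33 CPM in wild type, 14.2 ± 2.10 in Dpy30+/-, 57.8 ± 8.55 in Eu-Myc and 27.0 ± 5.03 in Eu-Myc Dpy30+/- (SD, n = 4). Dpy30 rose with the transgene by 1.27 on the log2 scale (SE 0.14, adjusted p = 1.58e-07) against wild type and by 0.93 (SE 0.14, adjusted p = 1.11e-05) in the Dpy30+/- background. It fell by 1.10 (SE 0.14, adjusted p = 0.00349) in Eu-Myc Dpy30+/- against Eu-Myc, a call that ended with spike-in scaling and in a fit of only these groups. Without the transgene its difference of -0.75 (SE 0.14) did not pass (edgeR adjusted p = 0.595), although the libraries of the groups did not overlap. Myc (ENSMUSG00000022346, chromosome 15, 61985341 to 61990361) stood at 119 ± 11.04, 136 ± 3.77, 1071 ± 139 and 1031 ± 54.4 CPM in the same order. Myc rose by 3.18 (SE 0.10, adjusted p = 1.13e-13) with the transgene in the wild-type background and by 2.92 (SE 0.10, adjusted p = 3.29e-13) in the Dpy30+/- background, counts in which the transcripts of the transgene and of the gene itself are not told apart. Between Eu-Myc Dpy30+/- and Eu-Myc, Myc differed by -0.05 (SE 0.09, adjusted p = 0.978).

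**Figure D1:**
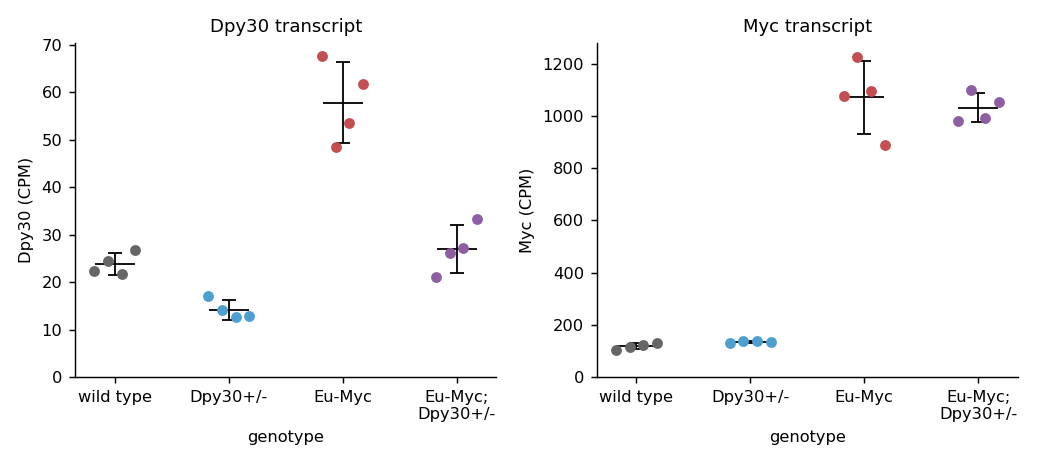
Dpy30 and Myc transcript levels (CPM, y axes) by genotype (x axes), with 1 point per library and the mean and SD of 4 libraries as lines. The Dpy30 means are 23.9, 14.2, 57.8 and 27.0 CPM, and the Myc means with the transgene are 1071 and 1031 CPM.

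Spike-in RNA was added per cell number, so the ratio of mouse gene counts to ERCC counts was taken as a measure of polyadenylated RNA per cell, which holds only where library preparation did not differ. The log2 ratio was 5.03 ± 0.26 in wild type, 4.85 ± 0.66 in Dpy30+/-, 6.67 ± 0.60 in Eu-Myc and 6.57 ± 0.39 in Eu-Myc Dpy30+/- (SD, n = 4). It was higher in all 4 Eu-Myc libraries than in all 4 wild-type libraries, by 1.64 or 3.11-fold (exact permutation p = 0.0286, adjusted p = 0.0571), and higher in Eu-Myc Dpy30+/- than in Dpy30+/- by 1.72 or 3.29-fold (exact permutation p = 0.0286, adjusted p = 0.0571). The smallest p these 70 assignments can give is 0.0286, and neither comparison passed after adjustment over the 4 comparisons. A test over both backgrounds, permuted within Dpy30 genotype and added after the data were seen, gave 1.68 or 3.20-fold (exact permutation p = 0.000408, the smallest its 4900 assignments can give). Dpy30+/- differed from wild type by -0.18 (exact permutation p = 0.857) and Eu-Myc Dpy30+/- from Eu-Myc by -0.10 (exact permutation p = 0.714). All libraries with the transgene came from 1 series of library numbers and all without it from the other. The transgene and a library batch therefore cannot be told apart in these ratios, nor in the gene changes between libraries with and without the transgene given below.

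**Figure D2:**
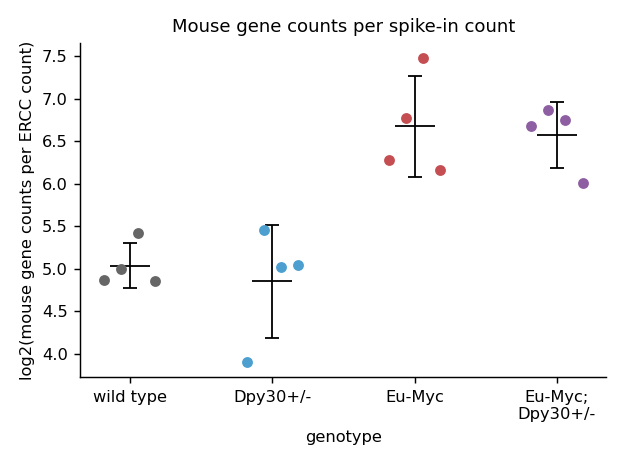
Log2 of mouse gene counts per ERCC spike-in count (y axis) by genotype (x axis), with 1 point per library and the mean and SD of 4 libraries as lines. The means are 5.03 and 4.85 without the transgene and 6.67 and 6.57 with it.

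The Eu-Myc against wild type comparison asks what the transgene changes in cells with both Dpy30 alleles intact. Relative to the median gene, the largest rises among genes with an average log2 CPM of at least 2 and no overlap between the groups' libraries, predicted genes and antigen receptor segments left out, were Car12, a membrane carbonic anhydrase (6.37, SE 0.23) and Bcat1, a branched-chain amino acid transaminase (6.35, SE 0.24), with n = 4 per group. They were followed by Eps8l2 at 5.97 (SE 0.30), Hspa12b at 5.67 (SE 0.22), Ankrd13b at 5.29 (SE 0.12), Crmp1 at 4.88, Ptgr1 at 4.85, Dnph1 at 4.73, Nt5dc2 at 4.64 and the ubiquitin hydrolase Uchl1 at 4.63. Under the same limits the largest falls were the phosphatase Ptpn14 (-4.72, SE 0.32), St8sia6 (-4.61, SE 0.24), the MAP kinase phosphatase Dusp4 (-4.45, SE 0.22), the adhesion molecule Alcam (-4.22, SE 0.19) and the transcription factor Bhlhe40 (-4.18, SE 0.12). They were followed by Tnik at -4.11, Cd200 at -4.06, Fcer2a at -4.01, Gpr174 at -3.98 and Hs3st1 at -3.91. The adjusted p-values of these 20 genes all lay at or below 8.95e-09. Of 14601 genes tested, 5479 rose and 5339 fell (10818, 74.1%), 2332 and 2792 of them by over 2-fold, and 11046 had an unadjusted p under 0.05. The groups' libraries did not overlap in 10033 genes (68.7%), where chance gives 2.86%. Scaling to spike-ins shifted the median gene by 1.61 and gave 10800 genes higher and 443 lower, with 1939 of the 7860 genes called under both scalings called in the opposite direction. The changes that follow are therefore relative to the median gene and the median per spike-in is given where the sign differs.

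Growth and division genes rose together. All 34 tested G2/M and mitosis genes rose (median 3.00), among them Aurkb at 2.92, Mybl2 at 2.99, Foxm1 at 2.45 and the separase Espl1 at 3.20 (camera adjusted p = 1.05e-14, and 0.177 with an estimated correlation). Of 40 genes of the G1/S transition and DNA replication, 39 rose and 1 fell (median 2.17), with the replication factors Mcm10 at 3.58, Mcm7 at 2.55 and Rfc4 at 2.42 and the phosphatase Cdc25a at 1.75 (camera adjusted p = 2.83e-14, and 0.173 with an estimated correlation). All 30 nucleotide synthesis genes rose (median 1.71), including the CTP synthase Ctps at 2.27 and the folate-cycle enzymes Shmt1 at 2.98, Mthfd2 at 2.14 and Shmt2 at 2.12 (camera adjusted p = 7.44e-13, and 0.173 with an estimated correlation). All 40 ribosome biogenesis genes rose (median 1.38), including Gnl3 at 2.33, Wdr12 at 1.77, the pseudouridine synthase Dkc1 at 1.76 and Ppan at 1.74 (camera adjusted p = 2.83e-14, and 0.173 with an estimated correlation). All 33 genes of mitochondrial chaperones, import and oxidative phosphorylation rose (median 1.22), with Hspd1 at 2.14, C1qbp at 1.94, Trap1 at 1.52 and Timm50 at 1.49 (camera adjusted p = 9.03e-11, and 0.190 with an estimated correlation). All 23 translation factors rose (median 1.12), with Eif2s1 at 1.59 and Eif4a1 at 1.53 (camera adjusted p = 3.79e-08, and 0.173 with an estimated correlation). Of 49 cytosolic ribosomal protein genes, 44 rose and 5 were not called (median 0.58), with Rpl14 at 0.97 and Rpl3 at 0.76 (camera adjusted p = 3.83e-06, and 0.470 with an estimated correlation). The polyamine synthesis list held related genes such as Eif5a beside the synthesis enzymes. Of its 10 genes 9 rose and 1 fell (median 0.84), with the spermidine synthase Srm at 2.51, Odc1 at 1.71, Eif5a at 1.69 and Amd1 at 1.30 (camera adjusted p = 0.00357, and 0.317 with an estimated correlation).

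Genes of B cell progenitors moved apart from those of mature B cells. Of 19 progenitor genes 14 rose and 2 fell (median 1.29), with the recombinase subunit Rag2 at 3.71, Myb at 2.63, Sox4 at 2.15 and Cecr2 at 1.47 (camera adjusted p = 0.00217, and 0.382 with an estimated correlation). Of 14 follicular B cell genes 12 fell and 2 were not called (median -1.74, and -0.09 per spike-in), with the low-affinity IgE receptor Fcer2a at -4.01, Il4ra at -2.54 and the chemokine receptor Cxcr5 at -2.23 (camera adjusted p = 1.09e-05, and 0.173 with an estimated correlation). Of 14 marginal zone genes 13 fell relative to the median gene (median -1.42, but 0.23 per spike-in), with Cd9 at -2.46 and Dtx1 at -2.13 (camera adjusted p = 1.10e-05, and 0.173 with an estimated correlation). Of 18 germinal centre and activation genes 17 fell and 1 rose (median -2.10, and -0.43 per spike-in), with Rgs13 at -4.22, Cd83 at -2.98 and Tnfaip3 at -2.16 (camera adjusted p = 6.07e-06, and 0.173 with an estimated correlation). All 16 NF-kappaB genes fell (median -1.91, and -0.26 per spike-in), with Bcl3 at -2.75, Relb at -2.04 and Nfkbie at -1.99 (camera adjusted p = 5.20e-07, and 0.173 with an estimated correlation). All 13 MHC class II presentation genes fell (median -1.68, and -0.02 per spike-in), with H2-Eb2 at -2.27, H2-Ob at -1.83 and H2-DMa at -1.69 (camera adjusted p = 2.68e-07, and 0.173 with an estimated correlation). Of 28 B cell receptor signalling genes 27 fell relative to the median gene (median -0.84, but 0.79 per spike-in), with Rasgrp3 at -3.45, the transcription factor Nfatc1 at -1.96 and the adaptor Bank1 at -1.91 (camera adjusted p = 5.17e-08, and 0.173 with an estimated correlation). Of 17 pan-B genes 14 fell and 2 rose (median -0.79, but 0.86 per spike-in), with Ptprc at -1.76 and Cd22 at -1.66, or 0.0090 for Cd22 per spike-in (camera adjusted p = 0.00152, and 0.173 with an estimated correlation).

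Among survival genes, 8 of 10 anti-apoptotic genes fell and 2 rose (median -0.82, but 0.82 per spike-in): Bcl2 fell by 2.95, Birc3 by 1.53 and Mcl1 by 1.05, or 0.13 for Birc3 and 0.59 for Mcl1 per spike-in, while Birc5, which also acts in mitosis, rose by 3.05 (camera adjusted p = 0.0160, and 0.190 with an estimated correlation). Of 21 pro-apoptotic genes 10 rose and 6 fell (median 0.20), with cytochrome c (Cycs) at 1.72 and Bbc3 at 1.57, and the list did not pass (camera adjusted p = 0.322). Of 29 p53 pathway genes 13 rose and 8 fell (median 0.16), with Gtse1 at 2.96, Plk2 at 1.49 and Tap1 at -1.29, or 0.33 for Tap1 per spike-in, and the list did not pass (camera adjusted p = 0.320). Among 11 CDK inhibitor and senescence genes 6 rose and 2 fell (median 1.29, camera adjusted p = 0.158), with Cdkn2a, which encodes p16 and p19ARF, at 4.78, the nuclear lamin Lmnb1 at 2.49, Cdkn2c at 2.11 and Rbl1 at 1.29. Cdkn2a stood at 0.257 ± 0.070 CPM in wild type and 7.11 ± 3.30 in Eu-Myc (SD, n = 4). Among 19 COMPASS subunits 9 rose and 6 fell (median 0.19, camera adjusted p = 0.255), with Paxip1 at 1.43, Wdr5 at 1.16, Psip1 at 1.15 and Ash2l at 1.05. In the Myc network 6 of 13 rose and 4 fell (median 0.13, camera adjusted p = 0.382), with Mxd3 at 2.39, Mxi1 at 1.33 and Mycl at -3.38. Of 23 glycolysis genes 15 rose and 7 fell (median 0.33, camera adjusted p = 0.0617), with the lactate transporter Slc16a1 at 3.12, Ldha at 2.06, Tpi1 at 2.04 and Pgam1 at 1.58.

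Interferon response and immediate-early genes and markers of other cell types were lower relative to the median gene. Of 22 interferon response genes 21 fell (median -1.48, but 0.09 per spike-in), with Gbp3 and Irf9 both at -1.19, or 0.45 and 0.44 per spike-in (camera adjusted p = 7.50e-07, and 0.190 with an estimated correlation). Of 20 immediate-early and dissociation stress genes 14 fell (median -0.81, but 0.80 per spike-in), with Nr4a1 at -1.79 (camera adjusted p = 0.000386, and 0.173 with an estimated correlation). All 11 NK cell genes fell (median -3.61, and -2.05 per spike-in), with the receptors Klrk1 at -3.68 and Klrb1c at -3.61, the granzyme Gzma at -3.64 and the transcription factor Tbx21 at -3.21 (camera adjusted p = 1.30e-06, and 0.173 with an estimated correlation). Of 18 T cell genes 17 fell (median -3.06, and -1.54 per spike-in), with Cd8b1 at -3.77 and Lck at -1.79 (camera adjusted p = 2.75e-07, and 0.173 with an estimated correlation). Of 15 dendritic cell genes 14 fell (median -2.80, and -1.38 per spike-in), with Klk1 at -4.75, Itgax at -3.47, Siglech at -3.09 and Flt3 at -2.11 (camera adjusted p = 2.59e-06, and 0.173 with an estimated correlation). Of 19 monocyte and macrophage genes 18 fell and 1 rose (median -1.72, and -0.06 per spike-in), with Ccr2 at -3.46, Lyz2 at -2.26 and Cd5l at -1.72 (camera adjusted p = 4.19e-06, and 0.190 with an estimated correlation). Of 11 stromal and endothelial genes 10 fell (median -1.42, but 0.23 per spike-in), with Kdr at -2.39 and Pecam1 at -1.39, or 0.23 for Pecam1 per spike-in (camera adjusted p = 0.0105, and 0.404 with an estimated correlation). Of 15 plasma cell genes 10 fell and 2 rose (median -1.05, but 0.65 per spike-in), with Jchain at -3.75, Prdm1 at -2.91, Ell2 at -2.24 and Slamf7 at 1.70, and the list did not pass (camera adjusted p = 0.0760). Of 17 erythroid genes 7 fell and 1 rose (median -1.46, but 0.42 per spike-in, camera adjusted p = 0.0784), and of 6 platelet genes 4 fell (median -1.22, but 0.36 per spike-in, camera adjusted p = 0.0864). Of 10 neutrophil genes 5 fell (median -0.94, but 0.56 per spike-in, camera adjusted p = 0.0882), and of 12 mitochondrially encoded transcripts 8 fell (median -0.38, but 1.30 per spike-in, camera adjusted p = 0.0864). None of these lists passed.

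Adjusted over the list alone, as many members passed in each list except the B cell progenitor (17), neutrophil (3), erythroid (2) and mitochondrially encoded (0, against 8 over all genes in edgeR) lists. In limma camera 24 of the 35 lists passed with the preset correlation (9 higher, 15 lower) and 0 with an estimated correlation, and 34 passed with fry. Without the 3 libraries that stand apart, the adjusted p with an estimated correlation was 0.0497 for ribosome biogenesis, follicular, marginal zone, germinal centre, NF-kappaB and dendritic cell genes, a result added after the data were seen. Under spike-in scaling the calls of Ptprc, Cxcr5, Dtx1, Relb, Tnfaip3, Ell2, Nfatc1, Bank1, H2-Ob, H2-Eb2, H2-DMa, Nfkbie, Nr4a1, Lck, Lyz2, Cd5l, Flt3 and Kdr no longer passed, with their direction kept.

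**Figure D3:**
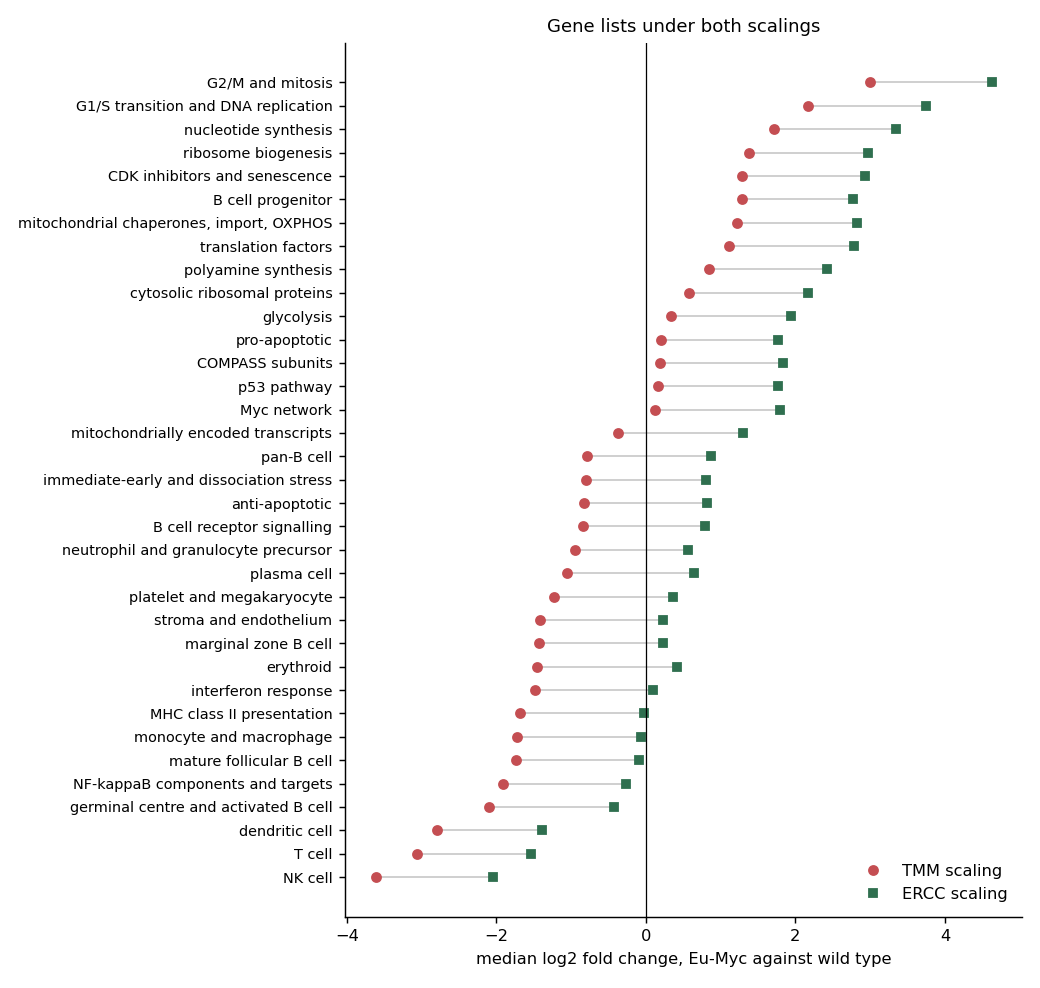
Median log2 fold change (x axis) of the members of each gene list (y axis) in Eu-Myc against wild type, with circles for TMM scaling and squares for scaling to ERCC spike-ins. The G2/M list lies at 3.00 and the NK cell list at -3.61 with TMM scaling, and lists such as MHC class II (-1.68) move to near 0 (-0.02) per spike-in.

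Eu-Myc Dpy30+/- against Dpy30+/- asks what the transgene changes where 1 Dpy30 allele is disrupted. Relative to the median gene and under the same limits, the largest rises were Car12 at 7.27 (SE 0.25), Eps8l2 at 6.67 (SE 0.33), Bcat1 at 6.56 (SE 0.24), Hspa12b at 5.65, Ankrd13b at 5.35, Dnph1 at 4.94, Crmp1 at 4.90, Ltbp4 at 4.75, Nav2 at 4.75 and Nt5dc2 at 4.46 (n = 4 per group). The largest falls under these limits were Ptpn14 at -3.96 (SE 0.31), Cd200 at -3.96, Dusp4 at -3.83, Bhlhe40 at -3.81, Alcam at -3.69, St8sia6 at -3.60, Hs3st1 at -3.55, Fcer2a at -3.54, the hepatic-type lipase Lipc at -3.52 and the transcription factor Stat4 at -3.42. All 34 G2/M genes, 39 of 40 G1/S genes, all 30 nucleotide synthesis genes and all 40 ribosome biogenesis genes rose, with list medians of 2.89, 1.93, 1.65 and 1.196. The adjusted p with an estimated correlation was 0.178 for G2/M and 0.162 for the other 3 lists. All 11 NK cell genes fell (median -2.26, and -0.55 per spike-in), as did 17 of 18 T cell genes (median -2.17, and -0.41 per spike-in), and all 13 MHC class II genes fell relative to the median gene (median -1.52, but 0.11 per spike-in). The adjusted p with an estimated correlation was 0.178, 0.178 and 0.162 for these lists. In all, 5307 genes rose and 4936 fell (10243 of 14601), 10578 had an unadjusted p under 0.05, and the groups' libraries did not overlap in 61.1% of genes. With the preset correlation 26 lists passed, 9 higher and 17 lower, and with an estimated correlation 0 passed (adjusted p from 0.162 to 0.635, 33 with fry). Scaling to spike-ins gave 11328 genes higher and 170 lower, with 1986 genes called in the opposite direction, and shifted the median gene by 1.61.

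The comparisons of libraries with and without the transgene called largely shared genes in both backgrounds. Of the genes that rose, 4976 did so in both, where independent calls give 1991, and of those that fell 4595 did so in both, where independent calls give 1805. No gene rose in 1 background and fell in the other (0 genes, edgeR calls in each comparison, expected 1852 and 1941), and the test of the difference itself, the interaction, passed for no gene (0 in edgeR and 0 in limma voom, 1 in DESeq2, with 448, 1259 and 453 at an unadjusted p under 0.05). Of the 10 named rises and 10 named falls, 8 and 8 were shared. Library numbers part in the same way in both backgrounds, so a library batch would be shared as well and cannot be told apart from the transgene here.

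**Figure D4:**
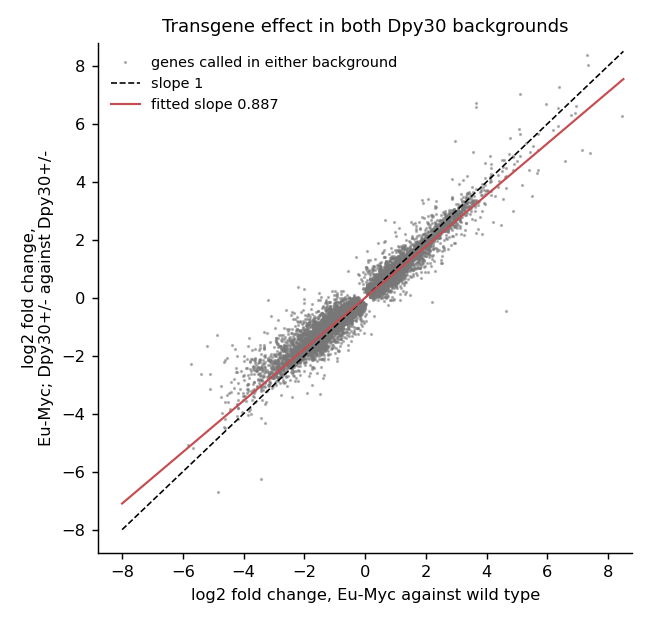
Log2 change with the transgene in the Dpy30+/- background (y axis) against that in the wild-type background (x axis), with 1 point per gene called in either background, a dashed line of slope 1 and a fitted line. The slope through the origin is 0.887 across 11490 genes with TMM scaling and 0.980 with spike-in scaling.

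Dpy30+/- against wild type asks what loss of 1 Dpy30 allele changes without the transgene. No gene passed in edgeR (0 of 14601, 219 at an unadjusted p under 0.05), and 1 gene, Dpy30, passed in DESeq2 (192 unadjusted) and in limma voom (886 unadjusted). Dpy30 differed by -0.75 (SE 0.14, adjusted p = 0.595) and Myc by 0.20 (SE 0.09, adjusted p = 1). The genes named for a small p did not pass either. They were Cxadr at -2.15 (SE 0.52), Evc at -1.54 (SE 0.39), Dnaaf3 at -1.03 (SE 0.27), Dnm3 at -1.04 (SE 0.27) and the cytidine deaminase Apobec1 at 0.27 (SE 0.08), each with an adjusted p of 1. Without the 3 libraries that stand apart Dpy30 passed (1 gene), and with spike-in scaling Ighg2b and Igkv5-39 passed (2 genes). Igkv5-39 took 22.0% of the Igkv counts of wild-type replicate 2, and whether its call rests on this 1 library was not tested.

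Some lists moved by small amounts in Dpy30+/- although none of their members passed. All 49 ribosomal protein genes were higher (median 0.13, but -0.07 per spike-in), such as Rps15 at 0.21 and Rpl15 at 0.15 (camera adjusted p = 3.48e-07, and 0.958 with an estimated correlation). Their median was -0.017 without the 3 libraries that stand apart. Interferon response genes were higher in 20 of 22 (median 0.18, but -0.0087 per spike-in), such as Rtp4 at 0.35 and Xaf1 at 0.25 (camera adjusted p = 2.46e-06, and 0.958 with an estimated correlation). Their median was 0.10 without Dpy30+/- replicate 1. Translation factors, the mitochondrial list, G1/S and G2/M had medians of 0.07, 0.06, 0.05 and 0.05, all below 0 per spike-in (-0.07, -0.07, -0.04 and -0.06), and plasma cell and T cell genes had medians of -0.11 and -0.29. With 1 library left out, the plasma cell median ranged from -0.183 (without wild-type replicate 3) to -0.033 (without wild-type replicate 2) and the T cell median from -0.430 (without wild-type replicate 4) to -0.110 (without Dpy30+/- replicate 4). In the same way translation factors ranged from 0.032 (without Dpy30+/- replicate 1) to 0.128 (without Dpy30+/- replicate 4), the mitochondrial list from 0.024 to 0.126 without these libraries, and G1/S from -0.0067 and G2/M from -0.077 (without wild-type replicate 1) to 0.131 and 0.188 (without wild-type replicate 2). In all, 8 lists passed with the preset correlation, while with an estimated correlation 0 passed (adjusted p = 0.958 for these lists) and with fry 0 passed. Adjusted over the list alone, 1 COMPASS gene passed, Dpy30, where 0 passed over all genes in edgeR. Spike-in scaling shifted the median gene by -0.135.

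Eu-Myc Dpy30+/- against Eu-Myc asks what loss of 1 Dpy30 allele changes in the presence of the transgene. Dpy30 itself was lower (-1.10) and 4 genes were higher, in all 4 libraries above all 4 Eu-Myc libraries. Klrb1c and Klrk1, which encode receptors of NK cells, rose by 1.59 (SE 0.23, adjusted p = 0.0187) and 1.24 (SE 0.20, adjusted p = 0.0470). The granzyme Gzma rose by 1.53 (SE 0.26, adjusted p = 0.0498) and Kcnip3, a calcium-binding protein, by 2.32 (SE 0.40, adjusted p = 0.0499). Klrb1c kept its call under 18 of 26 alternatives, Klrk1 under 8 of 26, Gzma under 7 of 26 and Kcnip3 under 1 of 24. Klrb1c stood at 0.859 ± 0.150 CPM in Eu-Myc and 2.58 ± 0.70 in Eu-Myc Dpy30+/- (SD, n = 4), against 10.5 ± 2.87 in wild type and 11.9 ± 1.00 in Dpy30+/-. Gzma stood at 2.63 ± 0.71 and 7.55 ± 2.75 CPM, against 32.4 ± 10.3 in wild type and 36.1 ± 3.48 in Dpy30+/-. Klrk1 stood at 0.941 ± 0.186 and 2.23 ± 0.58 CPM, against 12.1 in wild type, and Kcnip3 at 0.0548 and 0.293 CPM, against 1.11 in wild type. Not passing were Nkg7 at 1.57 (adjusted p = 0.0719), Runx2 at 1.08 (adjusted p = 0.102), Ncr1 at 1.68 (adjusted p = 0.105) and Ccr2 at 1.31 (adjusted p = 0.232).

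As a group, all 11 NK cell genes were higher (median 1.24, and 1.24 per spike-in), 3 of them past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 2.64e-29, and 0.0131 with an estimated correlation). Dendritic cell genes were higher in 14 of 15 (median 0.62), 0 past the edgeR threshold over all genes and 6 adjusted over the list alone, such as Runx2, Itgax at 1.25, Klk1 at 1.48 and Ccr9 at 0.84 (camera adjusted p = 1.48e-10, and 0.0131 with an estimated correlation). T cell genes were higher in 17 of 18 (median 0.88), 0 past the edgeR threshold over all genes and 7 adjusted over the list alone, such as Cd3e at 1.27, Cd8b1 at 1.16 and Cd8a at 0.97 (camera adjusted p = 3.29e-15, and 0.112 with an estimated correlation). All 10 neutrophil genes were higher (median 0.73), such as Mmp9 at 1.34 and Camp at 1.03 (camera adjusted p = 2.03e-05, and 0.361 with an estimated correlation). With an estimated correlation neither the NK nor the dendritic list passed without the 3 libraries that stand apart (adjusted p = 0.134 for both), without Eu-Myc replicate 2 (0.0966 for both) or without Eu-Myc Dpy30+/- replicate 4 (0.105 and 0.106), and the dendritic median was 0.37 without Eu-Myc Dpy30+/- replicate 1. The monocyte and macrophage list differed by a median of -0.07 (camera adjusted p = 0.226), with Ccr2 at 1.31 and Cd68 at -0.29.

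**Figure D5:**
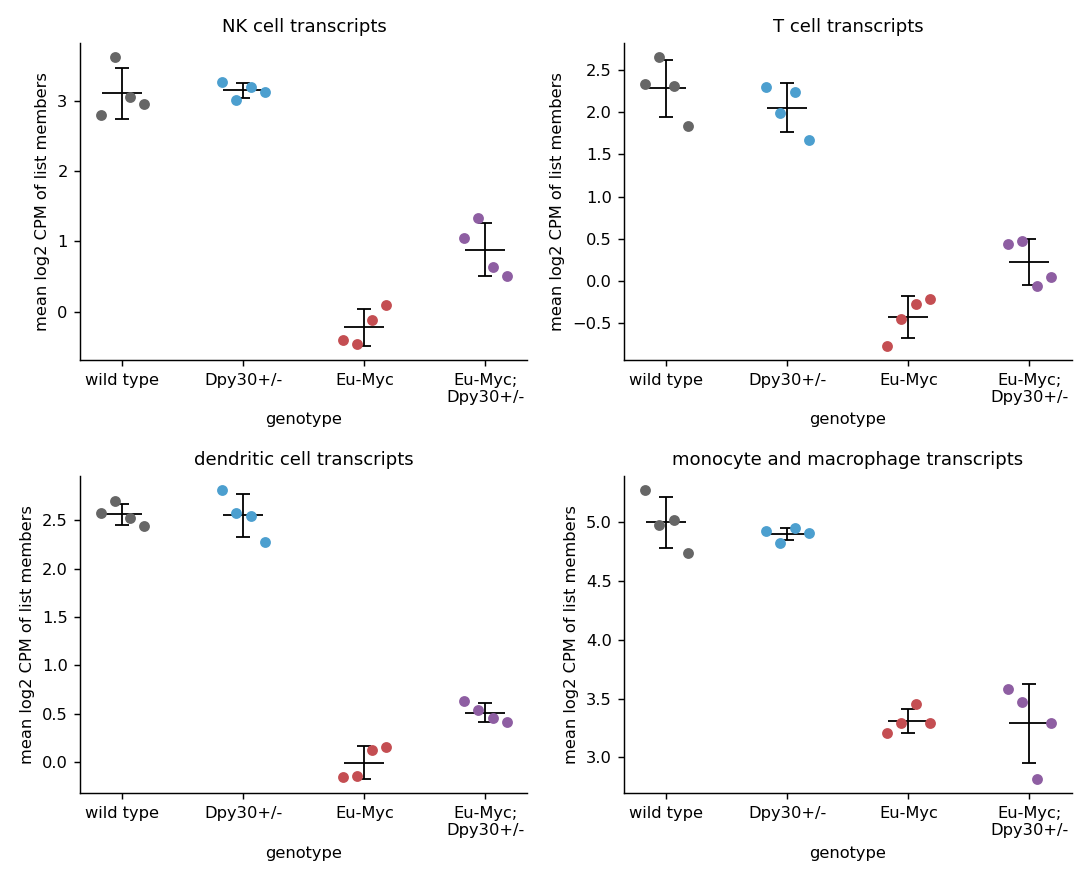
Mean level of the NK, T, dendritic, and monocyte and macrophage marker lists (y axes, log2 CPM) by genotype (x axes), with 1 point per library and the mean and SD of 4 libraries as lines. The median log2 fold change of the NK members is another measure and is not plotted here. It is 1.24 between Eu-Myc Dpy30+/- and Eu-Myc and -3.61 between Eu-Myc and wild type.

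Growth lists were lower and mature B cell lists higher by small medians. Ribosome biogenesis (-0.10), nucleotide synthesis (-0.09), polyamine synthesis (-0.11), translation factors (-0.10), ribosomal proteins (-0.07), the mitochondrial list (-0.12) and G1/S (-0.10) passed with the preset correlation, with adjusted p from 0.4998 to 0.740 with an estimated correlation. Follicular (0.16), marginal zone (0.16), germinal centre (0.14), MHC class II (0.14), NF-kappaB (0.13), interferon (0.15) and plasma cell (0.06) lists passed as well, with adjusted p from 0.4998 to 0.505 with an estimated correlation. Except for interferon (0.02), the medians of these B cell lists were at or below 0 per spike-in, from -0.10 for plasma cell to -0.00013 for marginal zone genes. Spike-in scaling moved the median gene by -0.14 in this comparison. In Eu-Myc replicate 1 the mean log2 CPM was 7.73 for ribosome biogenesis and 6.25 for follicular genes. The other Eu-Myc libraries had 7.49 to 7.50 and 6.84 to 6.90. Without that library 7 lists passed with the preset correlation, against 18 with it. Of the 35 splits of these libraries into groups of equal size, 13, the real one included, gave at least 18, so chance cannot be excluded.

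Of the 14601 genes 5 passed (4 higher, 1 lower), 464 had an unadjusted p under 0.05 and 262 (1.79%) had no overlap between the groups' libraries, where chance gives 2.86%. DESeq2 called 14, limma voom 1 (Dpy30), the fit of only these groups 0 (322 unadjusted) and edgeR with spike-in scaling 0 (94 unadjusted). Dpy30 passed with each library left out in turn. It was the only call without Eu-Myc replicate 1, 2 or 3 or Eu-Myc Dpy30+/- replicate 1 or 2, and 2 genes passed without wild-type replicate 3 or 4 or any 1 of the Dpy30+/- libraries. Without the 3 libraries that stand apart 3 genes passed.

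The interaction asks whether the effect of the Dpy30 alteration differs with the transgene. No gene passed in edgeR (0 of 14601, 448 at an unadjusted p under 0.05), 0 in limma voom (1259 unadjusted) and 1 in DESeq2, Klrk1 (adjusted p = 0.0412, 453 unadjusted). Among the genes with the smallest p, none of which passed, were Klrk1 at 1.30 (SE 0.26, adjusted p = 0.774), Klrb1c at 1.42, Kcnip3 at 2.20, Runx2 at 1.14, Nkg7 at 1.52 and Gzma at 1.38. Dpy30 differed by -0.35 (SE 0.19, adjusted p = 0.940) and Myc by -0.26 (SE 0.13, adjusted p = 0.940). NK cell genes had positive interactions in 11 of 11 (median 1.30, camera adjusted p = 1.12e-16, and 0.108 with an estimated correlation). Adjusted over the list alone 10 NK cell genes passed, against 0 over all genes in edgeR. T cell genes had positive interactions in 17 of 18 (median 1.13), such as Cd28 at 1.79 (camera adjusted p = 1.09e-12, and 0.185 with an estimated correlation). With the preset correlation 17 lists passed (9 higher, 8 lower), and 0 with an estimated correlation or with fry. Without Eu-Myc replicate 4, 1 gene passed, the immunoglobulin constant gene Igha.

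Across the 11490 genes called in either background, the transgene's changes in the Dpy30+/- background followed those in the wild-type background with a slope of 0.887 (r = 0.97 across genes, which are not independent replicates). Relabelling Dpy30 genotype within transgene status gave slopes of 1.00 ± 0.065 (SD), and 7 of 100 lay as far from 1. With spike-in scaling the slope was 0.980. The effects of the Dpy30 alteration with and without the transgene had a correlation of -0.074 across genes, and 54 of 100 relabellings lay as far from 0. Among genes with an average log2 CPM of at least 5 it was -0.378, and 38 of 100 relabellings, added after the data were seen, lay as far from 0. With the Eu-Myc libraries divided so that gene choice and effect shared none, the median effect of the Dpy30 alteration was -0.07 ± 0.05 on genes that the transgene raised and 0.09 ± 0.06 on those that it lowered (SD over 6 divisions, from -0.122 to -0.0036 and from 0.026 to 0.156). These medians were -0.045 and 0.063 without Eu-Myc Dpy30+/- replicate 1, and -0.113 and 0.134 without Eu-Myc Dpy30+/- replicate 4. Divisions that took Eu-Myc replicate 1, which stands apart, into the effect gave -0.122 to -0.103 and 0.138 to 0.156. Those that left it out of the effect gave -0.039 to -0.0036 and 0.026 to 0.041, so much of the size of both medians goes with this 1 library. In 20 simulations with no effect of Dpy30 genotype, the medians with shared Eu-Myc libraries were -0.0091 and 0.017, beside -0.07 and 0.10 in the data counted in the same way. The simulations drew each gene independently, so they held no shift shared by many genes of 1 library. They give the size of the bias from shared libraries only and cannot tell an effect of Dpy30 genotype from such shifts.

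Immunoglobulin variable gene use was spread over many genes in nearly all libraries. The most abundant Igkv gene took 10.1 ± 7.90% of Igkv counts in wild type, 5.87 ± 0.23% in Dpy30+/-, 5.50 ± 0.26% in Eu-Myc and 5.60% in Eu-Myc Dpy30+/- (SD, n = 4), where Igkv5-39 took 22.0% in wild-type replicate 2. The most abundant Ighv gene took 5.34, 4.99, 5.64 and 5.26% of Ighv counts. No comparison of these shares passed (exact permutation tests, adjusted p of 0.114 or more). For Igkv all Eu-Myc libraries lay below all wild-type libraries (exact permutation p = 0.0286), the smallest p that 70 assignments can give, so not passing says little there. Without wild-type replicate 2 the Igkv difference from wild type moved from -4.64 to -0.690 in Eu-Myc and from -4.26 to -0.317 in Dpy30+/-. Mitochondrially encoded transcripts took 5.19 ± 0.54% of counts in wild type, 5.43 ± 0.11% in Dpy30+/-, 3.63 ± 0.74% in Eu-Myc and 3.89 ± 1.03% in Eu-Myc Dpy30+/- (SD, n = 4). In both backgrounds all libraries with the transgene lay below all those without it (exact permutation p = 0.0286 for both, the smallest possible). Neither comparison passed after adjustment (exact permutation, adjusted p = 0.0571 for both).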

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

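The tests of explanations and the splits of samples in this part were chosen after the results were seen, except the test of sex for the libraries that stand apart, while the interaction tests of lists and the relabellings of the slope and of the correlation over all genes were planned.

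NK cell transcripts were higher in Eu-Myc Dpy30+/- than in Eu-Myc, by a median of 1.24 over 11 markers. Of the 35 splits of these 8 libraries 1, the real one, moved any list of at least 5 members as far (highest other 1.202, for the erythroid list). This argues against chance only narrowly and at the smallest share that 35 splits can give. The test was chosen after the NK result was seen, so it does not exclude chance. T cell (0.88), neutrophil (0.73) and dendritic (0.62) medians were higher too. The monocyte and macrophage list had a median of -0.075, and of at most 0.017 with 1 library left out. The SD of its members was 0.36, and 0.37 in the NK list, a spread between genes and not between libraries. These values argue against a lower share of B cells that raises every other cell type alike, as far as this list follows that share. With the transgene it fell less than the NK list, so it may not. A lower share that raises only some cell types stays open, untested here. Sex as the whole cause is argued against by the NK median of 1.43 between libraries of these genotypes that all lack Y-linked transcripts. A larger share of NK cells remaining in the B220+ sort may account for the NK markers, which were higher by 0.697 to 1.68, with Gzma, abundant in NK cells, at 7.55 CPM against 2.63, but as a hypothesis that leaves the T, neutrophil and dendritic lists unaccounted for. All 11 markers passed the count filter over the 16 libraries, which NK cells in the sort would also bring about, a change of expression per cell stays open, untested here, and the adjusted p with an estimated correlation ranged up to 0.134 over the alternatives.

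The ratio of mouse gene counts to spike-in counts was higher with the transgene. A few abundant genes taking most of the counts is argued against by the share of the 10 most abundant genes, 6.91 to 10.2% of a library's gene counts. Without immunoglobulin, haemoglobin and mitochondrial genes the difference was 1.68, beside 1.64 with them. That removal decides little, since abundant genes held so small a share. The library series and the transgene cannot be told apart, since 0 libraries part them. More RNA per cell with the transgene could account for the ratio and stays open beside the library series.

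Eu-Myc replicate 1 and Eu-Myc Dpy30+/- replicate 4 stood apart from their groups, and both held Y-linked transcripts. Sex acting alike in all genotypes is argued against by the slope of 0.039 between the Y-linked differences without and with the transgene, across 1928 autosomal genes (r = 0.177 across genes, which are not independent). Sequencing depth is argued against by gene counts within the range of the other libraries, at 28.3 M and 31.4 M, where the lowest library had 23.7 M. A sex difference that acts only with the transgene, or another difference between the animals could account for the pattern and stays open, untested here.

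Of 56 groups of 4 libraries over 14 measures, 6 held a library far from the other 3, where chance gives 2.8. The largest Igkv share was 22.0% in wild-type replicate 2, against 5.87 to 6.61% in the others. Non-unique alignments per gene count were 0.831 in Dpy30+/- replicate 1, against 0.648 to 0.672, and 0.921 in Eu-Myc Dpy30+/- replicate 4, against 0.791 to 0.807. Gzma stood at 41.25 CPM in Dpy30+/- replicate 1, against 33.6 to 34.9, and at 3.69 CPM in Eu-Myc replicate 4, against 2.21 to 2.37. Cdkn2a stood at 10.7 CPM in Eu-Myc Dpy30+/- replicate 4, against 5.01 to 5.79. In data that enter no gene test, non-unique alignments per gene count had a mean of 0.802 in Eu-Myc, above the wild-type range of 0.656 to 0.737.

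For 17 lists the effect of the Dpy30 alteration differed with transgene status by the interaction test with the preset correlation, and for 0 with an estimated correlation. The NK (1.30, adjusted p = 1.12e-16), T (1.13, adjusted p = 1.09e-12), dendritic (0.63, adjusted p = 4.31e-06) and neutrophil (0.53, adjusted p = 0.0334) lists had positive medians. So did the marginal zone (0.28, adjusted p = 0.00865), germinal centre (0.18, adjusted p = 0.0482), MHC class II (0.16, adjusted p = 0.0120), NF-kappaB (0.16, adjusted p = 0.0173) and plasma cell (0.15, adjusted p = 0.000857) lists. Medians were negative for ribosomal proteins (-0.20, adjusted p = 1.35e-08), G1/S (-0.18, adjusted p = 9.44e-06), translation factors (-0.18, adjusted p = 8.45e-05) and the mitochondrial list (-0.18, adjusted p = 5.83e-08). They were also negative for polyamine synthesis (-0.17, adjusted p = 0.00384), ribosome biogenesis (-0.14, adjusted p = 2.53e-06), nucleotide synthesis (-0.13, adjusted p = 0.00343) and G2/M (-0.091, adjusted p = 0.00858). In 17 of 100 relabellings, the real one included, some list lay as far from 0 as the NK list (1.30, farthest other 2.34, for the erythroid list), so chance cannot be excluded for the NK interaction. With an estimated correlation the adjusted p was 0.108 for the NK and dendritic lists, 0.185 for T and from 0.650 to 0.798 for the others.

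The real split called by far the most genes in Eu-Myc against wild type (10818, highest of the 35 splits otherwise 0). The same was seen in Eu-Myc Dpy30+/- against Dpy30+/- (10243, otherwise 0). The real split is 1 of 35, the smallest share the splits can give. Every other split puts libraries with and without the transgene into 1 group, which widens the spread within groups and favours a low count. The splits alone therefore do not exclude chance for these counts. A library batch that goes with the transgene is not excluded by these splits. In Eu-Myc Dpy30+/- against Eu-Myc the real split called the most genes (5, otherwise 2) and lists with an estimated correlation (2, otherwise 1). This does not exclude chance, since 1 of 35 is the smallest share the count can give. In addition, 1 of the 5 genes is Dpy30, whose disrupted allele defines the groups and favours the real split in advance. These calls are also fragile, since the count was 0 with ERCC scaling (edgeR, 94 at an unadjusted p under 0.05) and with only these groups (edgeR, 322). DESeq2 gave 14 and limma voom 1, and both lists had an adjusted p of 0.134 without the 3 libraries that stand apart. The calls ended where the p moved past the threshold, while the changes stayed about as large over the alternatives run (Dpy30 from -1.24 to -1.005, Klrb1c from 1.44 to 1.74, Klrk1 from 1.09 to 1.45, Gzma from 1.26 to 1.73 and Kcnip3 from 1.89 to 2.47). The real count was 0 in Dpy30+/- against wild type (edgeR, 219 at an unadjusted p under 0.05, 1 gene each in DESeq2 and limma voom) and in the interaction (edgeR, 448 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma voom). All 35 splits and all 100 relabellings reach a count of 0 by construction, so they say nothing about chance there, and the highest others were 4 and 1004. Relabellings that call so many genes point to a structure of the samples, as do splits that join Eu-Myc replicate 1 with Eu-Myc Dpy30+/- replicate 4. The 15 such splits gave 231 to 3230 genes at an unadjusted p under 0.05 (median 879, 10 of them above the 464 of the real split), and the 19 others gave 94 to 653 (median 264). For lists with the preset correlation, 16 splits reached the real count in Eu-Myc against wild type (24, highest other 28) and 7 in Eu-Myc Dpy30+/- against Dpy30+/- (26, highest other 29). Apart from the real ones, these splits exchange 1 library of each group and so still hold part of the group difference, while the 18 splits with 2 libraries of each group on both sides gave at most 11 and 10 lists, so the full set of splits does not decide these counts. Chance cannot be excluded for the list counts of Dpy30+/- against wild type (8, highest other 16, 20 splits as large), Eu-Myc Dpy30+/- against Eu-Myc (18, highest other 23, 13 splits) and the interaction (17, highest other 26, 20 of 100 relabellings). The same holds for the slope (0.887, farthest other 0.855, 7 of 100) and for the correlation of the effects of the Dpy30 alteration (-0.074, farthest other 0.278, 54 of 100; among genes with an average log2 CPM of at least 5, -0.378, farthest other -0.678, 38 of 100).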

How the results depend on the processing

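The fit with a term for Y-linked transcripts and the fit without the 3 libraries that stand apart were chosen after the data were seen. Over all alternatives, counts and values that answer a comparison kept their direction and side in 382 cases and moved in 49, and of 118 genes named in Eu-Myc against wild type 93 kept their call throughout and 25 lost it under some alternative, 7 of them with a change of sign, and 0 passed in the other direction. All 22 genes named in Eu-Myc Dpy30+/- against Dpy30+/- kept theirs under every alternative run. Of 19 genes named in Eu-Myc Dpy30+/- against Eu-Myc 8 stayed the same throughout, all 5 that passed lost their call under some alternative, and 5 others passed under some. Dpy30 kept its call under 24 of 26 alternatives, Klrb1c under 18 of 26, Klrk1 under 8 of 26, Gzma under 7 of 26 and Kcnip3 under 1 of 24, with changes that kept their direction (Kcnip3 from 1.89 to 2.47). Where no reason is given, the cause was not tested. No paired analysis was possible because the labels give no shared replicate numbers.

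In Dpy30+/- against wild type the count moved from 0 (edgeR, 219 at an unadjusted p under 0.05) to 2 with ERCC scaling, 1 in DESeq2, 1 in limma voom and 1 without the 3 libraries. In Eu-Myc Dpy30+/- against Eu-Myc it moved from 5 to 2 with RLE factors, 0 with ERCC scaling (edgeR, 94 unadjusted), 3 with no filter, 2 with a stricter filter, 14 in DESeq2, 1 in limma voom, 0 with only these groups (edgeR, 322 unadjusted, a fit of fewer libraries), 2 with the Y-linked term and 3 without the 3 libraries. It ranged from 1 without Eu-Myc replicate 1 to 6 without wild-type replicate 2. The interaction count was 1 in DESeq2 and ranged from 0 to 1, the latter without Eu-Myc replicate 4. With an estimated correlation, the lists that passed numbered 0 in Eu-Myc against wild type, 0 in Dpy30+/- against wild type, 2 in Eu-Myc Dpy30+/- against Eu-Myc, 0 in Eu-Myc Dpy30+/- against Dpy30+/- and 0 in the interaction. With fry they numbered 0, 2 and 0 in Dpy30+/- against wild type, Eu-Myc Dpy30+/- against Eu-Myc and the interaction. List counts ranged from 4 (without Dpy30+/- replicate 2) to 11 (without wild-type replicate 4) in Dpy30+/- against wild type, and from 7 (without Eu-Myc replicate 1) to 21 (without Eu-Myc Dpy30+/- replicate 4) in Eu-Myc Dpy30+/- against Eu-Myc.

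The slope was 0.980 with ERCC scaling, and the correlation of the effects of the Dpy30 alteration was -0.378 among genes with an average log2 CPM of at least 5. With ERCC scaling the median effects of the Dpy30 alteration were -0.136 on transgene-raised genes (from -0.569 to 0.389 over the 6 divisions) and 0.400 on transgene-lowered genes (from -0.368 to 1.19, a mean of 416 genes). Relative to all genes they were -0.030 and 0.505, beside -0.066 and 0.095 with TMM scaling. The log2 spike-in ratio of Dpy30+/- against wild type was 0.14 without the 3 libraries and ranged from -0.379 to 0.137 with each library left out, and that of Eu-Myc Dpy30+/- against Eu-Myc ranged from -0.269 to 0.169. The Igkv difference of Eu-Myc Dpy30+/- against Dpy30+/- was 1.09 for the 3 highest genes, and that of Eu-Myc Dpy30+/- against Eu-Myc ranged from -0.0978 to 0.274.

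List medians relative to all genes reversed where libraries were left out. In Dpy30+/- against wild type ribosomal proteins stood at -0.0135 without the 3 libraries and ranged from -0.0133 (without Dpy30+/- replicate 1) to 0.207, G1/S from -0.0022 (without wild-type replicate 1) to 0.134 and G2/M from -0.0727 (without wild-type replicate 1) to 0.191. In the same comparison the interferon list kept its call with each library left out. Translation factors lost theirs without wild-type replicate 1 or 3 or Dpy30+/- replicate 1, 2 or 3, the mitochondrial list without wild-type replicate 3 or Dpy30+/- replicate 1, and ribosomal proteins without Dpy30+/- replicate 1. G1/S lost its call without wild-type replicate 1 or 3 or Dpy30+/- replicate 2 or 3, and G2/M without wild-type replicate 1 or 3 or Dpy30+/- replicate 1, 2 or 3. Plasma cell genes lost theirs without wild-type replicate 2 or 4 or Dpy30+/- replicate 3 or 4, and T cell genes without wild-type replicate 2 or Dpy30+/- replicate 2 or 4. In Eu-Myc Dpy30+/- against Eu-Myc the erythroid list ranged from -0.395 (without Eu-Myc Dpy30+/- replicate 2) to 0.470. In the interaction G2/M ranged from -0.279 to 0.012 (without wild-type replicate 1) and germinal centre genes from -0.027 (without Eu-Myc replicate 1) to 0.265. In Eu-Myc against wild type, ERCC scaling changed the sign of Tap1 (0.33), Birc3 (0.13), Mcl1 (0.59), Cd22 (0.0090), Irf9 (0.44), Gbp3 (0.45) and Pecam1 (0.23), none of which passed in that direction, since it moved the median gene by 1.61.

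How far depth and group size limit the calls was not tested. In simulated data with 200 changed genes of an average log2 CPM of at least 2, 75.7% of genes changed 1.5-fold and 95.7% of those changed 2-fold were recovered. The adjusted threshold is stricter where few genes change, so these rates do not carry over to the Dpy30 comparisons. Without the transgene Dpy30 itself, at -0.75, had an unadjusted p of 4.08e-05 and an adjusted p of 0.595 in edgeR. Values at low levels such as Kcnip3 at 0.0548 CPM rest on few counts.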

Other observations

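The comparison in this part was computed after the results above were seen, and its groups are defined by Y-linked transcripts, not by the study. Among the 8 libraries with the transgene, the 2 with Y-linked transcripts (Eu-Myc replicate 1 and Eu-Myc Dpy30+/- replicate 4) were compared with the other 6, relative to the median gene with TMM scaling, the only scaling run for it. These 2 libraries had already been seen to stand apart, so the p-values that follow describe that difference and are no independent test of it. The smallest p belonged to Xist at -9.965 (edgeR adjusted p = 3.67e-06), followed by Kdm6a at -1.05 (adjusted p = 0.00068), and Kdm5c stood at -0.61 (adjusted p = 0.00382). Among other genes with a small p, named here without a fixed rule, the calcium-binding S100a6 was higher by 1.43 (adjusted p = 0.000969) and the cyclin Ccnd1 by 0.61 (adjusted p = 0.00123). The chemokine receptor Ccr6 fell by 1.497 (adjusted p = 0.00153), Tlr9, a sensor of DNA, by 0.79 (adjusted p = 0.00140) and Ciita, the activator of MHC class II genes, by 0.72 (adjusted p = 0.00123). No enrichment of any list was tested, and 15.8% of all autosomal genes changed. Of 33 mitochondrial chaperone, import and oxidative phosphorylation genes 22 changed (median 0.31), as did 29 of 49 ribosomal protein genes (median 0.27) and 10 of 12 mitochondrially encoded transcripts (median -0.65). Of 16 NF-kappaB genes 8 changed (median -0.40), as did 12 of 28 B cell receptor signalling genes (median -0.22) and 9 of 21 interferon response genes (median -0.34). Among further lists, 6 of 19 COMPASS, 4 of 17 pan-B, 3 of 13 MHC class II and 3 of 19 B cell progenitor genes changed. Other lists lay further from the share of all genes, with 6 of 10 polyamine synthesis and 6 of 10 anti-apoptotic genes. Lower counts were 0 of 13 Myc network, 0 of 12 T cell, 0 of 17 erythroid, 1 of 11 NK and 1 of 19 monocyte and macrophage genes. These are only some of the 35 lists.

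In all, 1959 of 12399 autosomal genes changed in that comparison (edgeR, 1065 higher, 894 lower). Among the 8 libraries without the transgene, 5 of which held Y-linked transcripts, 0 of 12701 autosomal genes passed (edgeR, 263 at an unadjusted p under 0.05, no other tool run). The difference between these comparisons was not tested. With 2 libraries on 1 side, the genes cannot be assigned to sex rather than to these libraries.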
